A study of Mus musculus with 663 samples.

How the data were processed

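Somatic cells of the developing mouse gonad were measured as single cells at 6 stages, from embryonic day 10.5 (E10.5) to postnatal day 6 (P6). Per the labels, all cells came from XX gonads of mice carrying an eGFP reporter of Nr5a1, which encodes a transcription factor of the gonadal somatic lineage. Per the labels' protocols, eGFP-positive live cells were sorted by flow cytometry and captured on C1 microfluidic chips. Their polyadenylated RNA was turned into cDNA with the SMARTer chemistry and into Nextera XT libraries. The labels state a depth of 10M paired reads of 100 bp per cell. The protocols name no molecular identifiers, so reads are not independent molecules.

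One table of 663 samples was used, each sample 1 cell. The authors' deposited values carried no unit name. They were taken as RPKM as deposited, that is reads scaled by the authors to gene length and library size, because their totals were neither fixed nor equal between cells. In addition, a median of 73.4% of the low values per cell, multiplied by gene length, fell within 0.02 of a whole multiple of the worth of 1 read, for genes of up to 6.5 reads. The gene lengths came from an annotation that may differ from that of the authors, so the reads behind each value were not recovered and no count model was used. Per the submitters' processing notes, the genome build was GRCm38.p3 (mm10). The aligner, the counting tool, its use of strand, the annotation release and any filter on cells are not given in the sources used here. Strand was not assumed, so reads of Xist and of its antisense partner Tsix could not be told apart, nor those of H19 and of Mir675, which lies within it.

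The table held 43347 gene names. Of these, 27 had been turned into dates by a spreadsheet and were left out. GENCODE vM21, an annotation of GRCm38, held 37915 of the names, and identifiers and positions were taken from it. One cell had a repeat library, which correlated with its first library at r = 0.996 across genes on the log2 scale, against a highest r of 0.802 for any other pair of cells. Both were averaged as 1 cell, which left 662 cells. No cell was removed in the main analysis. No doublet caller was run, and doublets were not marked in the labels. Each chip chamber was a separate library, but this does not show that each held 1 cell, so doublets were not excluded.

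Cells are not replicates, so the replicate was the capture, a chip run named in the sample titles. There were 12 captures, with 1 at E10.5, 3 at E12.5 and 2 at every other stage. The study's design text states 2 captures per embryonic stage other than E10.5, so the third E12.5 capture rests on the titles alone. The titles also name 2 sequencing series. The first held E10.5, E11.5, E13.5 and the first and second E12.5 captures, and the second held the third E12.5 capture, E16.5 and P6. E12.5 alone joined both series. The labels do not say whether captures of 1 stage came from separate litters, so p-values measure only the spread between captures, which may be technical.

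The choices of test, filter, pseudocount, gene lists, cell type markers and rule for named genes were made before the data were examined. For each capture, log2(mean RPKM over cells + 1) was computed, and 19710 genes with a capture mean of at least 1 RPKM in at least 1 capture were kept. Fold changes on this scale understate the change of genes at low levels. limma 3.58.1 in R 4.3.3 fitted stage and sequencing series to all 12 captures with an intensity trend, leaving 5 residual degrees of freedom. The E10.5 capture, without a replicate, took its spread from the other stages. The 5 consecutive stage comparisons and an overall F test were adjusted with the Benjamini-Hochberg method at 0.05. The comparison of E13.5 with E16.5 crosses the sequencing series and rests on the E12.5 captures through the series term. Since E12.5 alone sets that term, the fitted E12.5 level is that of its first and second captures. In tests on simulated data with 19710 genes and the spread of the real captures, log2 changes of 4 were recovered in 71.6% of genes for E10.5 to E11.5, in 83.6% for E12.5 to E13.5 and in 86.6% for E16.5 to P6. Log2 changes of 2 were recovered in 3.0%, 14.9% and 13.4% of genes, with 5, 5 and 4 false calls. The changed genes were drawn from those with a mean log2 value of at least 2, and the noise was normal and independent. These rates therefore do not cover genes near 0 in most captures, nor a capture that stands apart from the rest.

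In all, 26 gene lists with 311 genes were tested with the camera test of limma at its preset correlation of 0.01, two-sided, where at least 4 members were tested, and again with an estimated correlation. Counts of called members were taken over all genes and adjusted over the list alone. Genes were named by a rule: the 6 largest rises and 6 largest falls among called genes per comparison, without provisional names, the 3 called members of each list with the lowest adjusted p, and Nr5a1, Wt1, Gata4, Foxl2 and Nr2f2 in every comparison. Any other gene is said to have been chosen after its values were seen.

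Cells of all stages were clustered together with scanpy 1.11.5 in Python 3.11.15 on the natural logarithm of RPKM + 1, scaled per gene, using the 2000 most variable genes among those detected in at least 10 cells, 20 principal components, 15 neighbours and a Leiden resolution of 1. The plan had named the log2 scale here; the choice of variable genes in this tool takes natural logarithms, and scaling per gene removes the difference afterwards. The reporter itself and genes of the function and quality lists were left out of the clustering unless they were cell type markers. A cluster was named when at least 40% of a marker list was 2-fold higher than in the mean of the other clusters and at least 3 of the markers were detected in 25% of its cells. It was left unnamed if its 10 top genes held more markers of another cell type list than of its own. This condition and the thresholds were set after the data were seen. Shares of cells were given with exact Clopper-Pearson intervals at 95% and compared between stages by a permutation test over the 12 captures with 100000 resamples. A share of 0 was given with the limit that 3 cells would set. Intervals and limits cover counting error only. Changes within a class were tested with limma on captures with at least 5 cells of the class. The series term was fitted for pregranulosa-like cells and not for stroma-like cells, whose only such E12.5 capture was of the second series. Function lists were compared between 2 classes within each capture by an exact sign-flip permutation test.

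Alternatives were other pseudocounts of 0.1 and 10, no filter or a filter of 10 RPKM, no series term, the mean of log2 values over cells, upper quartile scaling, 20 cells with few detected genes left out, named somatic clusters alone, each series alone, other clustering settings and each capture left out in turn. An alternative written for count data was not run. Further alternatives were chosen after seeing the data: the second E12.5 capture left out together with the series term, a filter of at least 1 RPKM in at least 2 captures, and naming of clusters without the condition on top genes. The mean of log2 values was first run with a filter of its own, and over the genes of the main analysis only after that result was seen.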

Results

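The data held 662 single cells sorted for the Nr5a1-eGFP reporter from gonads labelled XX, in 12 captures of 40 to 71 cells. There were 71 cells at E10.5, 106 at E11.5, 163 at E12.5, 106 at E13.5, 95 at E16.5 and 121 at P6. In 11 captures the median depth, estimated from the smallest steps of the values, lay between 1.89M and 3.20M reads per cell, and the median number of detected genes between 3640 and 7976. The second E12.5 capture was shallower, with an estimated median of 0.152M reads and 3869 detected genes. Nr5a1 (chromosome 2 in GRCm38), the gene behind the reporter, was measured at every stage, at 19.6 RPKM at E10.5, 37.3 ± 8.42 at E11.5 (SD, n = 2 captures), 57.7 ± 13 at E12.5 (n = 3), 46.7 ± 12.1 at E13.5, 25.5 ± 7.16 at E16.5 and 19.4 ± 7.72 at P6 (n = 2 each).

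Transcripts of the sex chromosomes set 1 capture apart from its label. In the second E12.5 capture, labelled XX like the others, 40 of 53 cells held at least 1 Y-linked transcript (75.5%, exact 95% interval 61.7 to 86.2). In each other capture between 0 and 4 cells did, at most 5.63% (interval 1.56 to 13.8, E10.5). Captures with 0 such cells had 40 to 66 cells, which allows shares of up to 7.50% for the smallest. The mean of Ddx3y, a Y-linked RNA helicase gene chosen after its values were seen (chromosome Y, 1260771 to 1286629), was 20.6 RPKM in this capture and at most 0.099 RPKM in any other. Xist, the RNA that coats the inactive X chromosome and was also chosen after its values were seen (chromosome X, 103460366 to 103483254), was detected in 19 of its 53 cells, against 52 of 53 and 56 of 57 in the other E12.5 captures. Directions drawn from E12.5 below include this capture labelled XX unless stated otherwise. In fits with the series term the third E12.5 capture sets only that term. Log2 changes to or from E12.5 then rest on the first capture and this shallow second one alone. The RPKM means printed for E12.5 cover the third capture as well, so they can differ from the fitted changes.

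**Figure D1:**
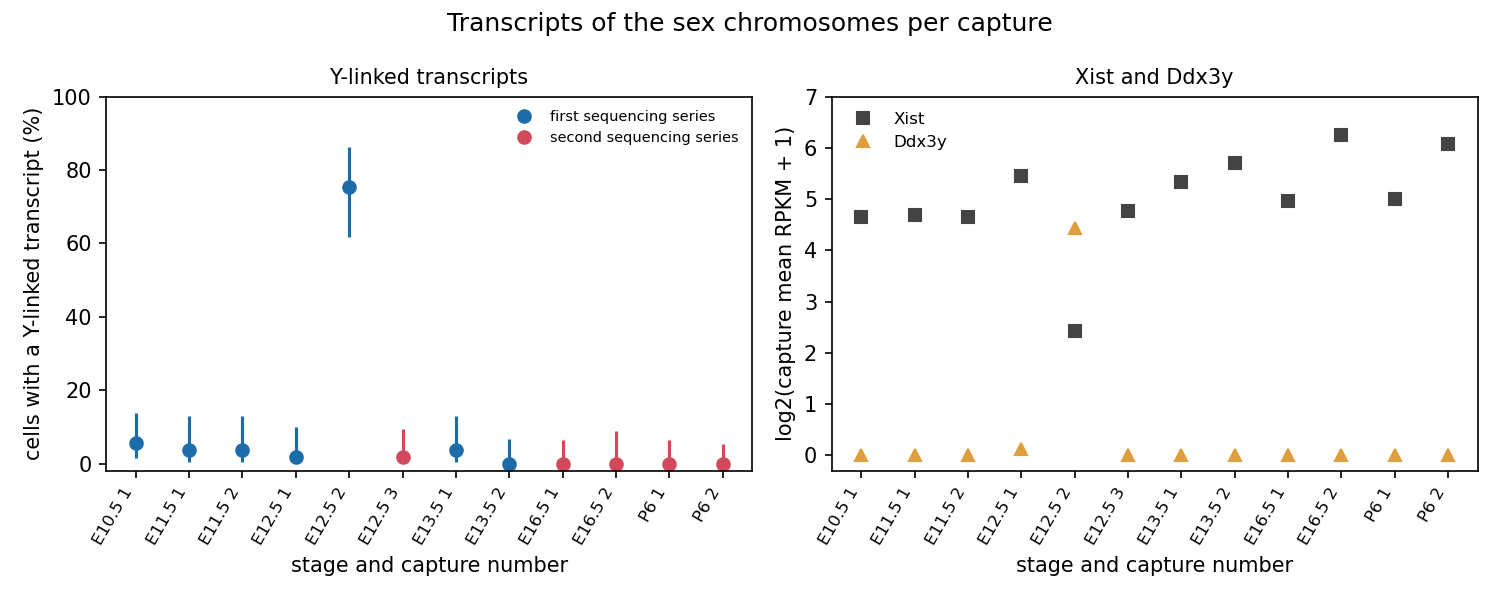
Left, share of cells with a Y-linked transcript in each of the 12 captures (points, percent of cells) with exact 95% intervals (bars), coloured by sequencing series. Right, capture means of Xist and Ddx3y as log2(RPKM + 1). The second E12.5 capture, at 75.5%, lies above the other captures, which reach at most 5.63%, and holds most Ddx3y (20.6 RPKM) and least Xist (4.39 RPKM).

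Clustering of all cells gave 10 clusters, of which 6 were named from fixed markers as 5 classes. Pregranulosa-like cells, with markers of the fetal supporting lineage such as Foxl2 and Fst, made up 0% of cells at E10.5 and E11.5, where 0 of 71 and 0 of 53 cells per capture allow up to 4.23% and 5.66%. They made up 6.65% ± 5.79 at E12.5 (SD, n = 3 captures), 51.9% ± 9.34 at E13.5, 51.5% ± 19.8 at E16.5 and 4.24% ± 1.71 at P6 (n = 2 each). Stroma-like cells, with interstitial markers such as Nr2f2 and Dcn, went from 0.943% ± 1.33 at E11.5 (n = 2) over 7.87% ± 4.26 at E12.5 (n = 3), 14.2% ± 6.67 at E13.5 and 29.7% ± 11.1 at E16.5 to 49.2% ± 5.36 at P6 (n = 2 each). Granulosa-like cells, with markers of growing follicles such as Amh and Hsd17b1, numbered 45 of 121 cells at P6 (37.9% ± 10.7, n = 2), 1 cell at E16.5 and 0 cells at the earlier stages, where 0 of 53 cells allows up to 5.66%. Surface epithelium-like cells, with keratins and Upk3b, made up 12.7% ± 11 at E12.5 (n = 3), 12.3% ± 1.33 at E13.5 and 3.98% ± 2.09 at E16.5 (n = 2 each). At this clustering resolution of 1 they were not found among 121 cells at P6, where 0 of 55 and 0 of 66 cells allow up to 5.45% and 4.55%.

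Mesonephros-like cells, with Lhx1 and Pax8, made up 84.5% of the single E10.5 capture and at most 7.55% of any other, so this cluster may stand for that capture as much as for a cell type. An unnamed cluster led by Asb4, Shisa3 and Mc2r held 70.8% ± 1.33 of E11.5 cells (n = 2). Shares differed between stages by the permutation test over 12 captures for stroma-like cells (adjusted p = 0.0262), this unnamed cluster (adjusted p = 0.0262), pregranulosa-like cells (adjusted p = 0.0374) and mesonephros-like cells (adjusted p = 0.0374). The adjusted p was 0.0752 for granulosa-like (unadjusted p = 0.0418 in the permutation test) and 0.297 for surface epithelium-like cells. Granulosa-like cells lay almost only in the 2 captures of P6. Such a pattern can hardly reach a lower p here, since permutations of 12 captures often enough put both into 1 stage. The 0.0752 is therefore not evidence against a difference. The remaining unnamed clusters had adjusted p values of 0.126, 0.811 and 1, and the last of these held 34 cells, 33 of them in the second E12.5 capture. Each of the 4 calls was lost when certain single captures were left out, with an adjusted p of up to 0.0775 for stroma-like cells and the unnamed cluster without the second E11.5 capture, 0.0827 for pregranulosa-like cells without the second E13.5 capture and 0.279 for mesonephros-like cells without the E10.5 capture. Without the second E12.5 capture the surface epithelium-like share passed (adjusted p = 0.0107). The sort for the reporter, and cluster genes that themselves differ between stages, also set these shares. Within the first series the pregranulosa-like share lay between 0% and 58.5% per capture, and within the second between 3.03% and 65.5%.

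The pregranulosa-like shares depended on a naming condition set after the data were seen. An unnamed cluster of 63 cells, led by Pnliprp2, Cpa1 and Chst4, had 6 of 12 pregranulosa markers 2-fold higher and met the marker thresholds. It stayed unnamed because its 10 top genes held more markers of another list. It made up 15.1% ± 2.67 of cells at E11.5 (n = 2) and 26.7% ± 13.6 at E12.5 (n = 3). Named without this condition, also chosen after seeing the data, pregranulosa-like cells made up 15.1% ± 2.67 at E11.5, 33.4% ± 19.3 at E12.5 and 54.7% ± 5.34 at E13.5. Their share then did not pass (adjusted p = 0.0664), so their absence at E11.5 is not established.

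Other clustering settings left stroma-like and granulosa-like cells at P6 between 47.7% and 50.2% and between 37.0% and 37.9%. The stroma-like share at E12.5 was 3.06% ± 2.86 at a resolution of 1.5 and 4.81% ± 4.45 with 1000 variable genes (SD, n = 3 captures), and both epithelial classes moved more. Pregranulosa-like cells made up 24.6% ± 6.78 at E12.5 at a resolution of 0.6, 20.1% ± 16.49 at 1.5 and 0.585% ± 1.01 with 10 principal components (SD, n = 3 captures). At a resolution of 0.6 they also made up 5.66% ± 5.34 at E11.5 and 12.9% ± 5.36 at P6 (n = 2 each), and at 1.5 and with 10 components 0% at P6. At E16.5 they made up 65.1% ± 10.8 at a resolution of 0.6, 34.7% ± 10.1 at 1.5 and 33.2% ± 4.5 with 10 components. Surface epithelium-like cells were most frequent at E11.5 at a resolution of 0.6 (77.4% ± 5.34) and at E16.5 at 1.5 (20.8% ± 11.7) and with 10 components (21.4% ± 16.1; n = 2 each). At P6 these last 2 settings gave them 3.48% ± 2.79 and 4.39% ± 4.07, so neither their peak nor their absence at P6 was stable.

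**Figure D2:**
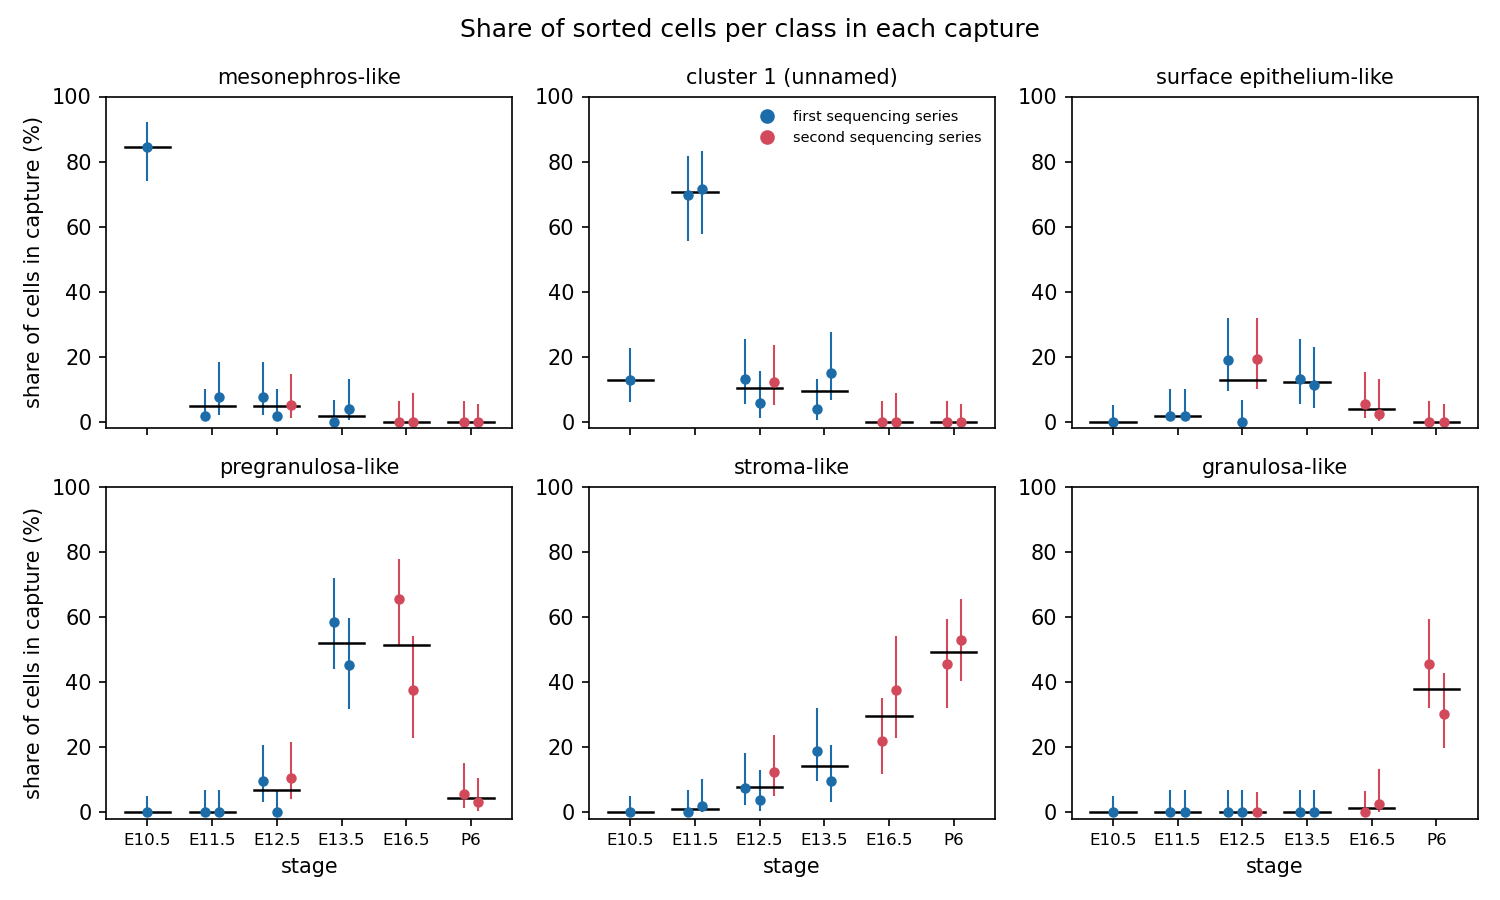
Share of cells per class (percent of the cells of a capture) by stage, for 5 named classes and 1 unnamed cluster. Points are captures, bars their exact 95% intervals, black lines stage means, and colours the sequencing series. Pregranulosa-like cells lie at 45.3% and 58.5% in the E13.5 captures and at 5.45% and 3.03% in the P6 captures, where granulosa-like cells lie at 45.5% and 30.3%.

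Between E10.5 and E11.5, Kctd14 (chromosome 7, 97451323 to 97459557) rose most among the called genes, from 0.0281 to 144 ± 53 RPKM (SD, n = 2; log2 change 7.09 ± 0.46 SE, adjusted p = 0.00179). Igf1, a growth factor gene and a stroma marker (chromosome 10, 87858265 to 87937042), rose from 0.801 to 33.4 ± 12 RPKM, and Ifitm1, an interferon-induced membrane protein gene, from 11.8 to 259 ± 57.3. Lin28a, which encodes an RNA-binding protein of early embryonic cells (chromosome 4, 134003330 to 134018841), fell from 37.5 to 0.4 ± 0.217 RPKM (log2 change -4.79 ± 0.42, adjusted p = 0.00531). Lhx1, a transcription factor gene of the nephric lineage (chromosome 11, 84518284 to 84525535), fell from 30.8 to 0.0453 ± 0.0613 RPKM (log2 change -4.93 ± 0.26, adjusted p = 0.00179). Vtn, which encodes vitronectin, fell from 40.8 RPKM and was listed at 0 in both E11.5 captures.

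In limma 191 of 19710 genes were called, 19 higher and 172 lower at E11.5. The other largest rises were Tulp2 (0.334 to 35.3 ± 5.23 RPKM), Cpne8 (0.132 to 27.1 ± 0.0192) and Rgcc (0.278 to 23.8 ± 12.6). The other largest falls were Sall1, a kidney transcription factor gene (28 to 0.105 ± 0.149 RPKM), Clec18a (14.3 to 0.00685 ± 0.00969) and Lyz1 (listed at 0 at E11.5, adjusted p = 0.00179). Called list members with small levels also fell, among them Pax2 of the nephric list (3.70 to 0.359 ± 0.363 RPKM), Cdh1 of the surface epithelium list (1.62 to 0.0146 ± 0.0151) and, all listed at 0 at E11.5, Grem1 (3 RPKM at E10.5), Cldn5 (2.74) and Shh (1.85). Among the genes named in every comparison, none passed: Nr5a1 had a log2 change of 0.88 ± 0.51, Wt1 1.06 ± 0.84, Gata4 1.05 ± 0.52, Foxl2 0.38 ± 0.84 and Nr2f2 -0.00 ± 0.56.

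Lists of cell cycle genes were lower at E11.5 than in the single E10.5 capture, whose spread was taken from other stages, so a difference of that capture alone was not excluded. The G2/M phase list fell (16 of 16 members lower, 0 called, camera adjusted p = 0.00016), with Top2a at 105 RPKM at E10.5 and 48.3 ± 3.87 at E11.5 and Cdk1 at 66.4 and 22.9 ± 3.08. The S phase list fell (17 of 18 lower, 0 called, adjusted p = 0.00529), with Rrm2 at 309 and 106 ± 39.4 RPKM. The mesonephros list fell (4 of 6 lower, 2 called and 2 adjusted over the list alone, adjusted p = 3.94e-05). Lists that rose were extracellular matrix (15 of 20 higher, 0 called, adjusted p = 0.0169), with Bgn, which encodes biglycan, at 1.61 and 19.5 ± 3.24 RPKM, stroma (12 of 17 higher, 1 called, adjusted p = 0.0215) and gonad progenitor (6 of 10 higher, 0 called, adjusted p = 0.0499), with Emx2 at 4.76 and 14.7 ± 1.46. Top2a, Cdk1, Rrm2, Bgn and Emx2 were chosen after their values were seen and did not pass alone. With an estimated correlation the adjusted p was 0.106 for mesonephros and 0.425 for each other list.

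The E10.5 group was 1 capture, and 154 of the 191 called genes exceeded 1 RPKM in 1 capture alone, so these calls rest mostly on that capture against the spread of genes that were near 0 elsewhere. With at least 1 RPKM required in at least 2 captures, chosen after seeing the data, and likewise with a filter of 10 RPKM, 1 gene was called, Kctd14. Within the first series alone limma called 0 genes, and 897 had an unadjusted p under 0.05. Without the first or second E11.5 capture the excess of lower genes was smaller. The comparison was then of 1 capture with 1, and most of the genes called exceeded 1 RPKM in 1 capture alone. Of the 17 named genes, 10 were called in each of the 10 fits that left out 1 capture. Neither the E10.5 capture nor the third E12.5 capture could be left out. Without the first E11.5 capture the adjusted p was 0.0994 for Cpne8, 0.0831 for Tulp2, 0.0733 for Rgcc, 0.0724 for Ifitm1 and 0.113 for Sall1. Without the first E16.5 capture it was 0.0784 for Pax2 and 0.0557 for Cdh1. Bgn passed without the first or second E12.5 capture (adjusted p = 0.0303 and 0.0314). Without the first E11.5 capture the adjusted p was 0.293 for S phase, 0.242 for extracellular matrix, 0.125 for stroma and 0.346 for gonad progenitor.

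Between E11.5 and E12.5 markers of the pregranulosa lineage were higher as a group (10 of 12 members higher, camera adjusted p = 0.00032; adjusted p = 0.845 with an estimated correlation). Of these, 0 were called over all genes and 3 adjusted over the list alone: Foxl2, a transcription factor gene of ovarian supporting cells (chromosome 9, 98955288 to 98958543), at 0.348 ± 0.492 RPKM at E11.5 (SD, n = 2) and 5.78 ± 3.23 at E12.5 (n = 3), Fst, which encodes the activin-binding protein follistatin, at 3.23 ± 0.578 and 37.5 ± 23.4, and Sprr2d at 0.0123 ± 0.00803 and 104 ± 105. The S phase list was lower (16 of 18 members lower, 0 called, adjusted p = 0.00173; adjusted p = 0.858 with an estimated correlation), with Rrm1 at 94.7 ± 8.46 and 37.2 ± 14.8 RPKM. Fst, Sprr2d and Rrm1 were chosen after their values were seen. Nr5a1 had a log2 change of 0.70 ± 0.41, Wt1 -0.50 ± 0.69, Gata4 -0.88 ± 0.42, Foxl2 2.42 ± 0.68 and Nr2f2 0.28 ± 0.46, and none passed.

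limma called 0 of 19710 genes between E11.5 and E12.5, with 1588 at an unadjusted p under 0.05, and within the first series alone also 0, with 1299. The latter fit takes E12.5 from the same captures as the main fit, so it is no separate check. Single captures decided this count: 1595 genes were called without the first E12.5 capture and 185 without the second. Of these, 275 and 134 exceeded 1 RPKM in 1 capture alone, and 859 and 65 had captures that did not overlap in the called direction. In both fits the series term took up the difference between the remaining E12.5 captures, so no spread within E12.5 entered. In the main fit that spread was the first capture against the second. Without the first or second E11.5 capture a single one was left there, and most genes called exceeded 1 RPKM in 1 capture alone. The pregranulosa list did not pass without the first E12.5 capture (adjusted p = 0.461), nor did the S phase list (adjusted p = 0.118), which also failed without the second E11.5 capture (adjusted p = 0.3). With the second E12.5 capture and the series term left out, chosen after seeing the data, 7 lists passed. Sprr2d passed without any one of the E11.5 captures or the first or second E12.5 capture (adjusted p = 0.0019 to 0.0121), and without the first E12.5 capture so did Wt1 (log2 change -1.673, adjusted p = 0.0375), Rrm1 (-2.058, adjusted p = 0.0409) and the Y-linked Ddx3y (4.431, adjusted p = 0.00152). That fit leans on the second E12.5 capture. Without the latter Wt1 had the opposite sign (0.667, adjusted p = 0.678), as did its stage means (136 and 144 RPKM), and Rrm1 had a log2 change of -0.864 (adjusted p = 0.665). Without the second E12.5 capture the G2/M phase list fell (adjusted p = 0.0086) and the surface epithelium list rose (adjusted p = 0.0382). The latter also passed without the second E11.5 capture (adjusted p = 0.0379).

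Between E12.5 and E13.5 Irx3, a pregranulosa transcription factor gene, stood at 4.72 ± 5.34 RPKM (SD, n = 3) and 10.7 ± 2.85 (n = 2), and Sprr2d at 104 ± 105 RPKM and listed at 0 in both E13.5 captures. Both passed when adjusted over the pregranulosa list alone and not over all genes. Sprr2d lay at 36.2, 50.8 and 225 RPKM in the E12.5 captures and under 0.03 RPKM in every capture of the other stages (adjusted p = 0.0115 in the overall F test). Gatm, which encodes the enzyme that makes guanidinoacetate, stood at 12.45 ± 9.60 and 102 ± 79.6 RPKM, and Fst at 37.5 ± 23.4 and 57 ± 3.31. Irx3, Sprr2d, Gatm and Fst were chosen after their values were seen. Nr5a1 had a log2 change of -0.39 ± 0.41, Wt1 0.76 ± 0.69, Gata4 0.84 ± 0.42, Foxl2 0.58 ± 0.68 and Nr2f2 -1.03 ± 0.46, and none passed.

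limma called 0 of 19710 genes between E12.5 and E13.5, with 1628 at an unadjusted p under 0.05, and within the first series alone also 0, with 1443. Again the latter fit takes E12.5 from the same captures as the main fit. Of the lists, 0 of 24 passed. Here too single captures decided the count: 1609 genes were called without the first E12.5 capture and 180 without the second, again with no spread within E12.5. Of these, 274 and 137 exceeded 1 RPKM in 1 capture alone, and 805 and 56 had captures that did not overlap in the called direction. Without the first or second E13.5 capture a single one was left there, and most genes called exceeded 1 RPKM in 1 capture alone. Without the second E12.5 capture 1 list passed, of immediate early and stress genes (adjusted p = 0.00434). Sprr2d passed without the first or second E12.5 capture or either E13.5 capture (adjusted p = 0.00201 to 0.0139), and without the first E12.5 capture so did Irx3 (adjusted p = 0.0225), Wt1 (log2 change 1.925, adjusted p = 0.0254), Gatm (adjusted p = 0.0261), Xist (adjusted p = 0.049) and Ddx3y (adjusted p = 0.00153). The last 2 mark the second E12.5 capture. Without that capture Wt1 had the opposite sign (-0.415, adjusted p = 0.902), and the adjusted p was 0.519 for Irx3 and 0.66 for Gatm.

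Between E13.5 and E16.5 Sugct, a coenzyme A transferase gene (chromosome 13, 16857472 to 17695553), rose from 0.0604 ± 0.0241 to 6.15 ± 1.05 RPKM (SD, n = 2 each; log2 change 2.70 ± 0.40, adjusted p = 0.0463). Chodl, which encodes the membrane lectin chondrolectin (chromosome 16, 78930948 to 78951733), was listed at 0 in both E13.5 captures and rose to 3.45 ± 0.324 RPKM (adjusted p = 0.0407). The extracellular matrix list rose (13 of 20 members higher, camera adjusted p = 0.0403; adjusted p = 0.840 with an estimated correlation), with Col1a1, a fibrillar collagen gene, at 26 ± 7.04 and 119 ± 32.5 RPKM. The list of immediate early and stress genes, induced by tissue dissociation among other things, also rose (11 of 14 higher, adjusted p = 0.0148; adjusted p = 0.840 with an estimated correlation), with Fos at 518 ± 16.4 and 751 ± 49.4 RPKM. The endothelial list fell (9 of 9 lower, adjusted p = 0.0148; adjusted p = 0.484 with an estimated correlation), with Emcn at 1.49 ± 0.774 and 0.000657 ± 0.000929 RPKM. Members called over all genes and adjusted over the list alone numbered 0 and 0 for extracellular matrix and for immediate early genes, and 0 and 2 for endothelial genes, Emcn and Cldn5.

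In limma 104 of 19710 genes were called, 4 higher and 100 lower at E16.5; the other higher genes were Gm22043 and Gm27813. The largest falls by fitted change had low levels: Pmis2 (1.84 ± 0.856 to 0.0796 ± 0.113 RPKM), Cacng5, a calcium channel subunit gene (1.89 ± 0.520 to 0.0155 ± 0.0219), Gja4, a gap junction gene (1.80 ± 0.457 to 0.00211 ± 0.00298), Serpinb7 (0.453 ± 0.640 to 0.00126 ± 0.00178), and, listed at 0 at E16.5, Tmem27 (0.222 ± 0.244) and Asb9 (0.148 ± 0.209). Cdh1, called lower among surface epithelium markers, was listed at 0 at E13.5 and stood at 0.000776 ± 0.0011 RPKM at E16.5. Of the 104 genes, 91 were under 1 RPKM in every E13.5 and E16.5 capture and 21 had captures that did not overlap in the called direction, so most of the calls came from the series term, which the E12.5 captures set. Emcn, Fos, Col1a1, Gm22043 and Gm27813 were chosen after their values were seen. Nr5a1 had a log2 change of -0.58 ± 0.65, Wt1 -0.66 ± 1.08, Gata4 -1.73 ± 0.67, Foxl2 0.41 ± 1.08 and Nr2f2 0.28 ± 0.72, and none passed. The signs for Wt1 and Foxl2 went against their stage means (160 and 194 RPKM, 10.8 and 9.78 RPKM) and turned round without the second E12.5 capture (0.511 and -0.18).

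Without the series term limma called 0 genes between E13.5 and E16.5 (1132 at an unadjusted p under 0.05), and with a filter of 10 RPKM it called 0 (525 at an unadjusted p under 0.05). Without a filter it called 568. Within the second series the third E12.5 capture against E16.5 gave 0 in limma, with 1563 at an unadjusted p under 0.05. The excess of lower genes was not stable: 348 were higher and 438 lower without the first E12.5 capture, and 74 and 115 without the second. Of these calls 371 of 786 and 163 of 189 exceeded 1 RPKM in 1 capture alone, as did 81 of 104 in the main fit. Without the first or second E16.5 capture the excess was smaller too. A single capture was then left in that stage, and most genes called exceeded 1 RPKM in 1 capture alone. The number called was 0 without the E10.5 capture, 210 and 216 without the first or second E11.5 capture, 786 and 189 without the first or second E12.5 capture, 275 and 268 without either E13.5 capture, 219 without the second E16.5 capture and 191 without the second P6 capture. Leaving out the E10.5 capture ended the call of each named gene (adjusted p = 0.146 for Sugct and 0.158 for Chodl). As the lone capture of its stage it adds nothing to these log2 changes (2.7 for Sugct) or to the 5 residual degrees of freedom. Without it only the genes kept (19437) and the spread that limma pools over genes differed. Each of the 3 lists failed without certain captures, with an adjusted p of 0.609 for extracellular matrix and 0.139 for endothelial genes and for immediate early genes without the second E16.5 capture. The G2/M phase list passed as higher without the first E13.5 or the first E16.5 capture (adjusted p = 0.0263 and 0.0016), but without the series term it passed as lower (mean log2 change -1.025, adjusted p = 0.00427). Fos passed without the first E12.5 capture (adjusted p = 0.0345).

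Between E16.5 and P6 genes of growing follicles rose. Hsd17b1, an enzyme gene of oestradiol synthesis (chromosome 11, 101078411 to 101080527), rose from 0.140 ± 0.197 to 69 ± 44.4 RPKM (SD, n = 2 each; log2 change 5.79 ± 0.58, adjusted p = 0.0202). Inha, which encodes the inhibin alpha subunit (chromosome 1, 75507077 to 75510366), rose from 22 ± 3.71 to 1281 ± 716 RPKM (log2 change 5.69 ± 0.61, adjusted p = 0.0228). Amh, the anti-Müllerian hormone gene, was listed at 0 in both E16.5 captures and rose to 7.06 ± 1.98 RPKM (adjusted p = 0.0114). Nr5a2, an orphan nuclear receptor gene, rose from 0.00251 ± 0.00355 to 11.2 ± 2.38 RPKM (adjusted p = 0.011), and Esr2, which encodes oestrogen receptor beta, from 1.42 ± 0.22 to 23 ± 4.10 (adjusted p = 0.0275). Of the 16 markers of growing granulosa cells, 15 were higher, these 5 were called over all genes and 10 adjusted over the list alone (camera adjusted p = 6.31e-15; adjusted p = 0.138 with an estimated correlation).

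Lect1 had the largest rise of all, from 0.00432 ± 0.00611 to 170 ± 108 RPKM (log2 change 7.25 ± 0.64, adjusted p = 0.0114). It encodes a secreted cartilage glycoprotein, and the annotation used here held no gene of this symbol. Stromal matrix genes rose too: Ogn, which encodes osteoglycin (chromosome 13, 49608046 to 49624501), from 2.93 ± 2.54 to 179 ± 11.51 RPKM (log2 change 5.69 ± 0.59, adjusted p = 0.0203), and Mfap5, a microfibril gene (chromosome 6, 122505845 to 122529290), from values listed at 0 to 40.6 ± 9.26 (adjusted p = 0.00838). Apoa1, the main apolipoprotein gene of high-density lipoprotein, rose from 0.565 ± 0.605 to 55.6 ± 11.3 RPKM. Ptch1, the Hedgehog receptor and target gene, rose from 2.58 ± 2.14 to 44.7 ± 0.373 RPKM (adjusted p = 0.0406), and Cdh5, an endothelial cadherin gene, from 0.0427 ± 0.0604 to 8.21 ± 2.21 (adjusted p = 0.0284).

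Among the falls, Pglyrp1, a peptidoglycan recognition protein gene, went from 62.8 ± 47.1 to 0.245 ± 0.296 RPKM (log2 change -5.47 ± 0.68, adjusted p = 0.0397) and Tm4sf5 from 29.2 ± 8.70 to 0.00348 ± 0.00493 (log2 change -4.88 ± 0.55, adjusted p = 0.0275). H19, an imprinted noncoding RNA gene (chromosome 7, 142575529 to 142578143), fell from 420 ± 33.5 to 24.1 ± 17.8 RPKM (log2 change -4.28 ± 0.58, adjusted p = 0.0492). Igf2, the imprinted growth factor gene beside it (chromosome 7, 142650766 to 142666816), fell from 46.1 ± 7.90 to 2.34 ± 0.910 RPKM (log2 change -3.84 ± 0.31, adjusted p = 0.011). Mir675 (96 ± 17.3 to 2.83 ± 2.33 RPKM) lies within H19 and shares its reads. Slc46a3 fell from 7.94 ± 2.73 to 0.00112 ± 0.00158 RPKM.

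**Figure D3:**
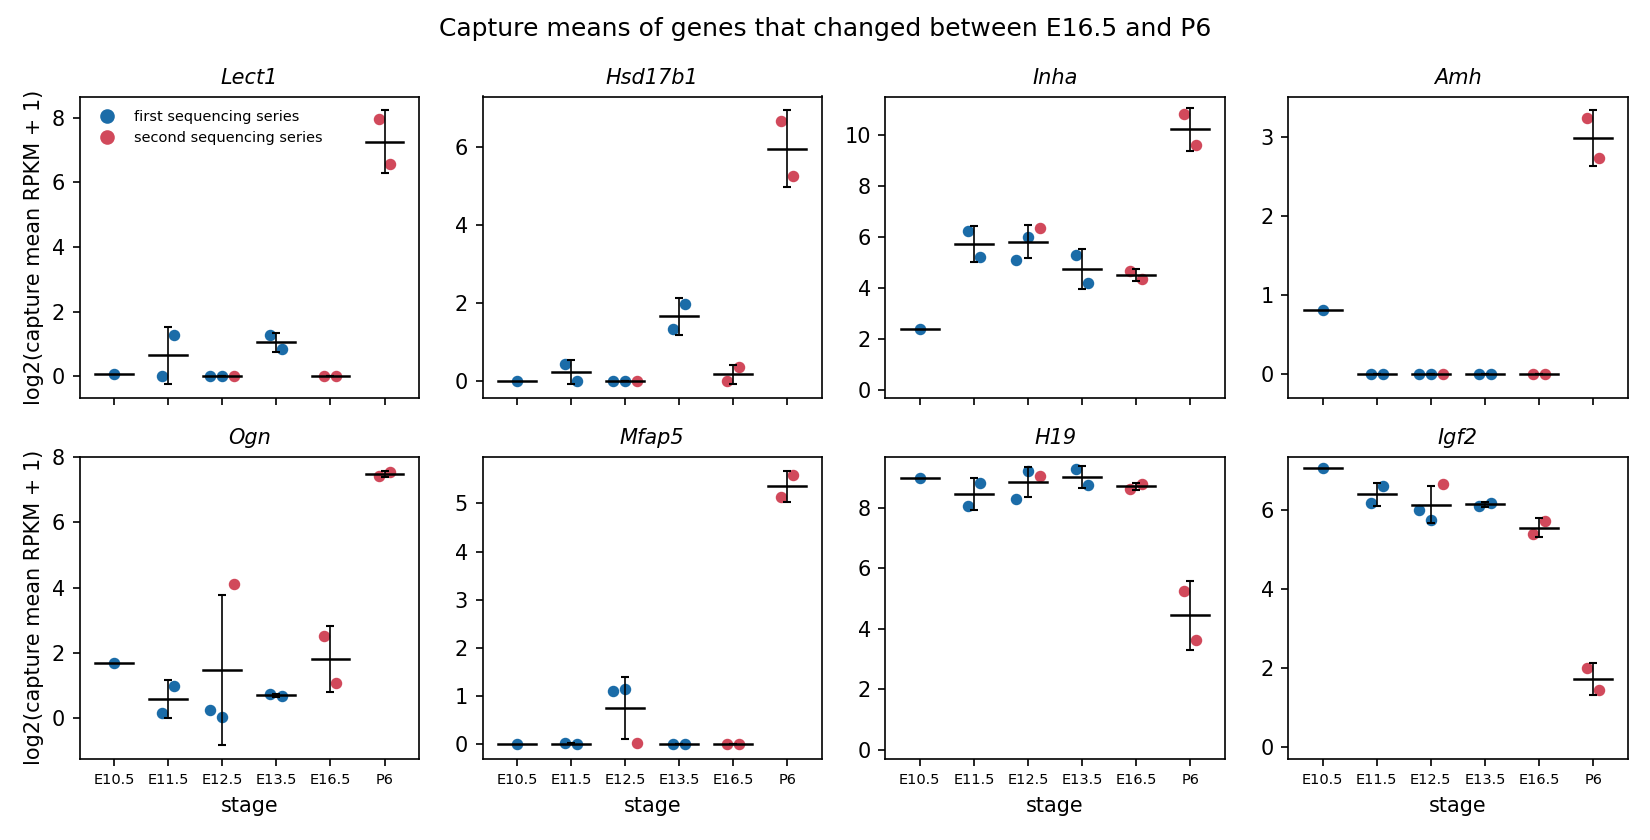
Capture means of 8 genes called between E16.5 and P6, as log2(RPKM + 1), by stage. Points are captures coloured by sequencing series, black lines the stage means and error bars 1 SD over captures. In both P6 captures Lect1, Hsd17b1, Inha, Amh, Ogn and Mfap5 lie above, and H19 and Igf2 below, both E16.5 captures.

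Surface epithelium markers fell as a group at P6 (13 of 13 lower, 0 called over all genes, 9 adjusted over the list alone, camera adjusted p = 3.35e-11; adjusted p = 0.138 with an estimated correlation). Upk1b, a uroplakin gene, stood at 26.4 ± 5.53 and 0.00151 ± 0.00214 RPKM and the keratin gene Krt19 at 40.7 ± 26.2 and 0.284 ± 0.401. The Wnt signalling list fell (11 of 14 lower, 0 called, 3 adjusted over the list alone, adjusted p = 8e-04; adjusted p = 0.299 with an estimated correlation). Rnf43 stood at 6.79 ± 0.566 and 0.157 ± 0.202 RPKM and Lgr5, which is also a surface epithelium marker, at 16.2 ± 5.84 and 0.108 ± 0.111. The pregranulosa list (10 of 12 lower, 0 called, 2 adjusted over the list alone, adjusted p = 0.0421; adjusted p = 0.358 with an estimated correlation) and the gonad progenitor list (8 of 10 lower, 0 called, 1 adjusted over the list alone, adjusted p = 0.0297; adjusted p = 0.295 with an estimated correlation) fell too. Gng13 stood at 208 ± 0.941 and 6.30 ± 0.410 RPKM and Lhx9 at 20.1 ± 2.89 and 4.01 ± 3.

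The G2/M phase list rose at P6 (15 of 16 higher, 0 called, adjusted p = 0.000697; adjusted p = 0.403 with an estimated correlation), with Ccnb2 at 15.6 ± 2.54 and 50.4 ± 11.4 RPKM. The S phase list had 9 of 18 members higher (adjusted p = 0.953). Extracellular matrix rose (15 of 20 higher, 0 called, adjusted p = 0.00134; adjusted p = 0.299 with an estimated correlation), with Col6a3 at 5.08 ± 0.211 and 18.1 ± 1.65 RPKM. So did Hedgehog signalling (7 of 10 higher, 1 called, 2 adjusted over the list alone, adjusted p = 0.0106; adjusted p = 0.206 with an estimated correlation). Stroma markers (12 of 17 higher, 2 called, 2 higher and 1 lower adjusted over the list alone, adjusted p = 0.0297; adjusted p = 0.388 with an estimated correlation) and Notch signalling (7 of 8 higher, 0 called, 2 adjusted over the list alone, adjusted p = 0.0438; adjusted p = 0.299 with an estimated correlation) rose as well. Heyl stood at 1.69 ± 0.465 and 25.1 ± 20.1 RPKM. The cell cycle inhibitor list did not pass (adjusted p = 0.191), with Cdkn1a at 24.4 ± 6.02 and 0.621 ± 0.807 RPKM and Cdkn1c at 429 ± 255 and 27.1 ± 4.63. Upk1b, Krt19, Rnf43, Lgr5, Gng13, Lhx9, Ccnb2, Col6a3, Heyl, Cdkn1a and Cdkn1c were chosen after their values were seen and did not pass alone.

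In limma 57 of 19710 genes were called between E16.5 and P6, 40 higher and 17 lower at P6. All 57 had captures that did not overlap. So had all genes called in each fit that left out 1 capture, so this follows from the call and is no added support. Nr5a1 had a log2 change of -0.40 ± 0.41, Wt1 -0.97 ± 0.69, Gata4 -0.48 ± 0.42, Foxl2 1.32 ± 0.68 and Nr2f2 0.64 ± 0.46, and none passed. Within the second series alone, a fit chosen after seeing the data, limma called 0 genes, with 1564 at an unadjusted p under 0.05. With named somatic clusters alone limma called 0, with 1967 at an unadjusted p under 0.05. With a filter of 10 RPKM the count was 22. In settings chosen after seeing the data it was 52 with at least 1 RPKM in at least 2 captures, and 119 with the second E12.5 capture and the series term left out, of which 45 were among the 57. The count was 36 without the E10.5 capture, 28 or 26 without the first or second E11.5 capture, 20 or 19 without the first or second E13.5 capture, 184 or 270 without the first or second E16.5 capture and 285 or 369 without the first or second P6 capture. Leaving out a capture of another stage changed the estimate of spread and the genes kept, but not the log2 changes of this comparison. Leaving out an E16.5 or a P6 capture left 1 capture in that stage. Most of the genes then called exceeded 1 RPKM in 1 capture alone, against 0 of 57 in the main fit. The balance of higher and lower genes turned with the capture left out, but for this reason it does not bear on the direction of the 57. Of the named genes, Mfap5, Apoa1, Igf2, Nr5a2 and Amh were called in each of the 11 fits that left out 1 capture. H19 was lost in 8 of these 11 fits (adjusted p up to 0.126, without the second E11.5 capture). Without the first E13.5 capture the adjusted p was 0.0503 for Lect1, 0.0613 for Hsd17b1, 0.0647 for Inha, 0.0758 for Ogn and Tm4sf5, 0.0734 for Esr2, 0.0977 for Ptch1, 0.0768 for Cdh5, 0.102 for Pglyrp1, 0.114 for Mir675 and 0.0625 for Slc46a3. Cdkn1a passed without the second P6 capture (adjusted p = 0.0304) and Cdkn1c without the first or second E12.5 capture (adjusted p = 0.0454 and 0.0487). Granulosa, surface epithelium and Wnt lists passed in each of the 11 fits that left out 1 capture. Without the first E16.5 capture the adjusted p was 0.506 for stroma and for G2/M phase, 0.32 for extracellular matrix and 0.236 for the Hedgehog, Notch, pregranulosa and gonad progenitor lists.

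Over all stages 271 of 19710 genes were called by the overall F test of limma. They included Sprr2d of the pregranulosa list and 5 of 16 markers of growing granulosa cells. With at least 1 RPKM required in at least 2 captures, chosen after seeing the data, 15 were called. The count was 1 without the E10.5 capture, 644 or 664 without the first or second E11.5 capture and 1412 or 618 without the first or second E12.5 capture. It was 462 or 472 without either E13.5 capture, 421 without the second E16.5 capture and 482 or 682 without the first or second P6 capture. These lists did not pass in any of the 5 comparisons: mitochondrially encoded genes (adjusted p = 0.0775 to 0.656), germ cell markers (adjusted p = 0.191 to 0.977) and blood and immune markers (adjusted p = 0.297 to 0.991). The same held for Sertoli cell markers (adjusted p = 0.638 to 0.977), steroidogenic markers (adjusted p = 0.0562 to 0.977) and perivascular markers (adjusted p = 0.537 to 0.977). Lists for TGF-beta and BMP signalling (adjusted p = 0.128 to 0.977), cholesterol synthesis (adjusted p = 0.151 to 0.977) and hormone receptors (adjusted p = 0.0581 to 0.779) did not pass either. Mitochondrially encoded genes passed as lower at E11.5 without the first E11.5 capture (adjusted p = 0.0152) or the first P6 capture (adjusted p = 0.0497), and as higher at P6 without the first P6 capture (adjusted p = 0.00437). Hormone receptors passed as higher at P6 without the second E16.5 or the second P6 capture (adjusted p = 0.0431 and 0.0338). Adrenal cortex and Y-linked lists had 3 tested members each, too few for the test.

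Within single classes limma called 0 genes in each of the 4 comparisons that had enough cells. Among pregranulosa-like cells 3076 of 16268 genes had an unadjusted p under 0.05 between E12.5 and E13.5 and 2732 between E13.5 and E16.5. Among stroma-like cells 1037 of 15881 did between E13.5 and E16.5 and 1004 between E16.5 and P6. The stroma-like fit had no series term, so its comparison of E13.5 with E16.5 was also one of the first series with the second. In the pregranulosa-like fit the E12.5 level rested on 5 cells of the first E12.5 capture. Its series term rested on these against 6 cells of the third. Without that term, a setting chosen after seeing the data, 1870 genes had an unadjusted p under 0.05 between E12.5 and E13.5. Between E13.5 and E16.5 the number was then 698, and 0 genes were called in either comparison. H19 and Igf2, carried over from the stage comparison after their values were seen, differed within stroma-like cells from 424 ± 107 to 22.5 ± 9.76 RPKM (SD, n = 2 each; log2 change -4.22 ± 0.52) and from 33.9 ± 9.99 to 2.99 ± 0.112 (log2 change -3.10 ± 0.71), with limma adjusted p of 0.551 and 0.578. Different clusters held most stroma-like cells at E16.5 and at P6. Without the first or the second P6 capture 556 or 720 genes were called, of which 549 or 702 exceeded 1 RPKM in 1 capture alone. For the change from E13.5 to E16.5 in pregranulosa-like against stroma-like cells, limma called 0 of 14366 genes (786 with an unadjusted p under 0.05, smallest adjusted p = 0.869). This test had 4 captures and 2 residual degrees of freedom, so differences were not excluded.

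In the 5 captures with at least 5 cells of both classes, pregranulosa-like and stroma-like cells were compared in 10 function lists, none of which passed. Extracellular matrix genes were lower in pregranulosa-like cells by a mean log2 difference of -2.36 ± 0.42 (SD, n = 5 captures, lower in 5 of 5), and 16 of the 20 members were lower in every capture. Col1a1 stood at 5.76 ± 3.87 RPKM in pregranulosa-like and 194 ± 102 in stroma-like cells, and Bgn at 8.54 ± 7.08 and 147 ± 39.2. Cell cycle inhibitors were higher (log2 difference 0.97 ± 0.36, 5 of 5 captures; 4 of 10 members higher in every capture), with Cdkn1c at 627 ± 154 and 185 ± 46.7 RPKM and Cdkn1a at 22.3 ± 13.7 and 1.72 ± 3.82. G2/M phase genes had a difference of -1.92 ± 1.97 (lower in 4 of 5 captures). Top2a stood at 6.30 ± 10.47 and 51.8 ± 40.1 RPKM. Cholesterol synthesis genes were higher (0.93 ± 0.60, 5 of 5 captures), with 4 of 19 members higher in every capture. The sizes depended on the pseudocount. At 0.1 they were 1.68 for cholesterol synthesis, 1.38 for inhibitors, -2.58 for G2/M phase and -2.85 for extracellular matrix. Hmgcs1, an enzyme gene of the early pathway, stood at 274 ± 105 and 60.5 ± 24 RPKM, while Sqle and Insig1 were higher in 1 of 5 captures. The named members were chosen after their values were seen. Median detected genes were 6128 in the pregranulosa-like cluster and 4631 and 3798 in the stroma-like ones. Cells averaged per capture differed too, with 36 and 12 in the first E16.5 capture. The effect of this was not tested. The inhibitor difference was 0.33 in the second E16.5 capture (15 cells of each class) and 1.16 in the third E12.5 capture (6 and 7 cells). For cholesterol synthesis these captures had 1.07 and 0.53.

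TGF-beta and BMP signalling genes (0.99 ± 0.50, or 1.45 with a pseudocount of 0.1) and Wnt signalling genes (0.88 ± 0.35, or 1.69) were higher in pregranulosa-like cells in 5 of 5 captures. But 7 of 16 and 3 of 14 of these genes were themselves cell type markers. Without marker genes, a step chosen after seeing the data, the differences were -0.19 and 0.28. Hormone receptors were lower in 5 of 5 captures by a small difference (-0.12 ± 0.13), which was -0.38 without marker genes and 0.14 with a pseudocount of 0.1. The differences were -0.21 ± 0.34 for Notch signalling, -0.11 ± 0.37 for Hedgehog signalling and -0.46 ± 0.88 for S phase, with captures on both sides of 0. In the 3 captures with at least 10 cells of both classes S phase had a difference of -1.02 ± 0.34 and was higher in 0 of 3. With 5 captures the smallest exact p that the two-sided sign-flip test allows is 0.0625, reached by 6 of the 10 lists (adjusted p = 0.104), so no list could pass the threshold.

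**Figure D4:**
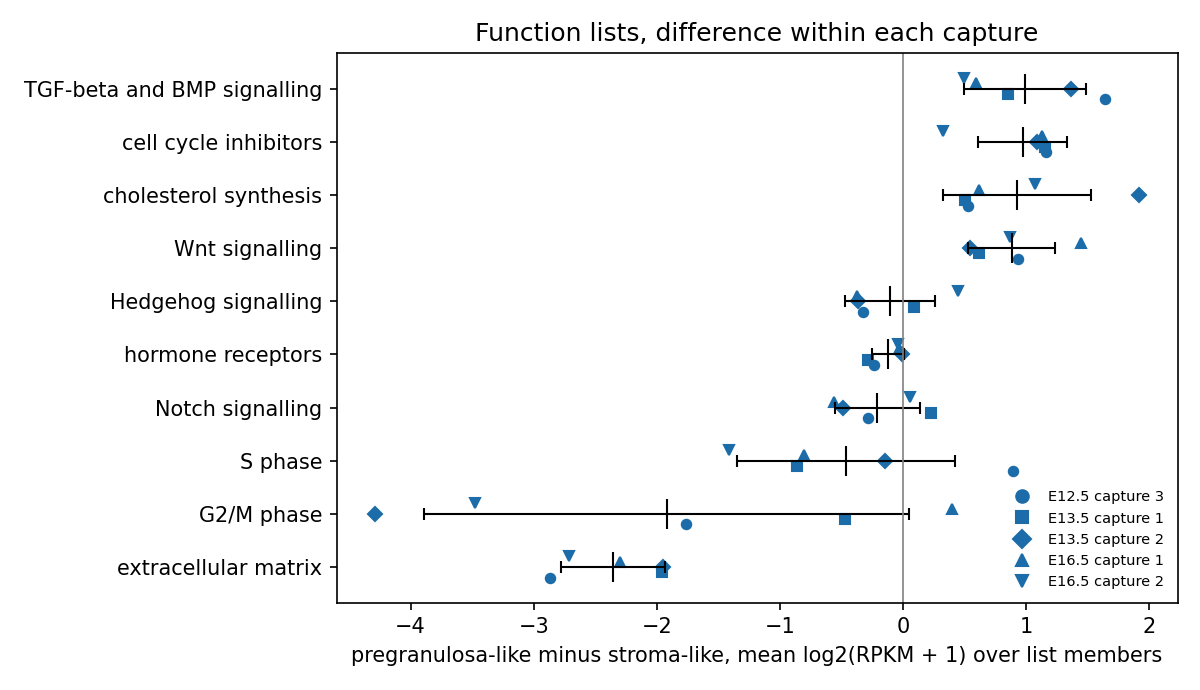
Difference between pregranulosa-like and stroma-like cells (x axis, mean log2(RPKM + 1) over list members) for 10 function lists (y axis). Symbols are the 5 captures, vertical ticks their means and horizontal bars 1 SD. Extracellular matrix lies below 0 in all 5 captures, with a mean of -2.36, and cell cycle inhibitors above 0 in all 5, with a mean of 0.97.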

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

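All tests on the Y-linked transcripts in this part were chosen after the result was seen, as was the test of abundant genes for H19 and Igf2; the test within stroma-like cells was chosen before.

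The second E12.5 capture, labelled XX, stood out because 75.472% of its cells held a Y-linked transcript, far above the limit that 0 cells would set in a capture of its size (5.66%). Low depth of this capture does not account for the Y-linked transcripts, since fewer reads cannot raise their share above that of the deeper captures, whose intervals end at 13.8% or below. Reads carried over from other libraries stay open: the highest share in another capture of the first series was 5.634%, but this is the contrast that singled out the capture, and those captures were deeper, so it does not bound what may have entered a shallow one. The level of Xist is less clear. Its ratio to the other E12.5 captures lay at the percentile 8.01 among 774 genes of similar level and length. That test left low depth open for the whole capture. But 1 cell with 212 RPKM and 599 detected genes made up most of the mean, and without it the mean was 0.397 RPKM. Over the 40 cells with a Y-linked transcript the ratio was 0.0088, below the 5th percentile of 0.0797 among the same genes (percentile 0.517). This comparison was made only after 8.01 was seen, and it argues against low depth alone for these cells. XY cells remain a candidate explanation as a hypothesis. These 40 cells had a mean Xist of 0.305 RPKM, against at least 24.1 over all cells of every other capture. Where other captures held cells with a Y-linked transcript, 1 to 4 each, the mean Xist of those cells lay between 6.17 and 38.8 RPKM. A biological difference was not tested.

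H19 and Igf2 were lower at P6 than at E16.5. The prediction written for a changed mix of cell classes failed within stroma-like cells, where the gene of the pair nearer to 0 had a log2 change of -3.097 ± 0.71. Neither gene was called there (limma adjusted p = 0.551 for H19 and 0.578 for Igf2). Different clusters held these cells at either stage, so this test cannot exclude a changed mix within the class. Other classes were not compared between these stages. The prediction for a shift of the deposited scaling that lowers all abundant genes was not met. The median log2 change was -0.106 over 1288 other genes of at least 50 RPKM at E16.5. Values scaled to library size leave this median little room to fall, so the test says little about such a shift. Median totals per cell were 408305 and 392203 RPKM in the E16.5 captures and 402984 and 413259 in the P6 captures. A change with age, which the design names, stays open as an untested hypothesis, and of 11 fits that left out 1 capture the H19 call was lost in 8 and the Igf2 call in 0. Where H19 was lost without an E11.5, E12.5 or E13.5 capture, its log2 change stayed at -4.278. Those captures enter this comparison only through the estimate of spread and the genes kept. Without the first or second E16.5 capture the log2 change of H19 was -4.359 or -4.197.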

How the results depend on the processing

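The settings named here as added, and the settings of the overall F test other than the pseudocounts, the series term and the captures left out, were chosen only after the data were seen. Counts of called genes follow the order E10.5 to E11.5, E11.5 to E12.5, E12.5 to E13.5, E13.5 to E16.5, E16.5 to P6 where 5 are given. Without a filter they were 1003, 42, 24, 568 and 102 (1509 over all stages), with a filter of 10 RPKM 1, 0, 0, 0 and 22 (18), and with at least 1 RPKM in at least 2 captures (added) 1, 1, 1, 0 and 52 (15), the single genes being Kctd14 in the first comparison and Sprr2d in the next 2 comparisons. Without the series term they were 95, 0, 0, 0 and 65, and with the second E12.5 capture also left out (added) 109, 1, 0, 0 and 119. The mean of log2 values with its own filter, which was run first, gave 443, 34, 61, 1 (Arl5a) and 190 (1483); over the main genes, made after that result was seen, it gave 445, 0, 0, 0 and 128 (489). A pseudocount of 0.1 gave 45 for E13.5 to E16.5. Named somatic clusters gave 0 for each of the last 3 comparisons and could not be fitted for the first 2. The first series alone gave 0 for E10.5 to E11.5 (added), and the second alone 0 for E12.5 to E16.5 and 0 for E16.5 to P6 (added). The causes were not tested, except that fewer genes entered under the stricter filters and fewer captures under a single series.

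Leaving out 1 capture at a time gave 154 to 388, 0 to 1595, 0 to 1609, 0 to 786 and 19 to 369 called genes, and 1 to 1412 over all stages; the lone capture of a stage was assumed to vary like the others. Called lists ranged from 3 to 7, 0 to 4, 0 to 1, 0 to 4 and 3 to 10. Within classes the range was 0 to 0 for pregranulosa-like cells in both comparisons and for stroma-like cells between E13.5 and E16.5, and 0 to 720 for stroma-like cells between E16.5 and P6. Without the third E12.5 capture the series term could not be estimated, so no fit was made over all cells or for pregranulosa-like cells; for the latter this also held without the first. Share tests had adjusted p of 0.0689 to 0.191 for granulosa-like, 0.0253 to 0.279 for mesonephros-like, 0.0253 to 0.0827 for pregranulosa-like, 0.0184 to 0.0775 for stroma-like and 0.0107 to 0.498 for surface epithelium-like cells, and 0.0227 to 0.0775, 0.0227 to 0.255, 0.468 to 1 and 0.835 to 1 for unnamed clusters 1, 2, 4 and 7. The log2 differences of function lists ranged from -0.805 to -0.227 for S phase, -2.50 to -1.33 for G2/M phase, 0.93 to 1.13 for inhibitors, 0.68 to 1.03 for cholesterol synthesis, 0.74 to 0.97 for Wnt, -0.32 to -0.12 for Notch, -0.24 to -0.04 for Hedgehog, 0.83 to 1.12 for TGF-beta and BMP, -2.46 to -2.23 for extracellular matrix and -0.15 to -0.08 for hormone receptors.

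With an estimated correlation 0 lists passed in every comparison. Without the series term 6 lists passed for E11.5 to E12.5 and 6 for E13.5 to E16.5, and with the second E12.5 capture also left out (added) 7, 4 and 6 for E11.5 to E12.5, E12.5 to E13.5 and E13.5 to E16.5. The G2/M phase list turned round, to a mean log2 change of -1.025 for E13.5 to E16.5 in both of these settings and of 0.802 for E12.5 to E13.5 in the second, and Cdh1 to 0.001 for E13.5 to E16.5 in both. At a clustering resolution of 0.6 the share test gave an adjusted p of 0.0489 for granulosa-like and 0.022 for surface epithelium-like cells, and at 1.5 it gave 0.0501 for mesonephros-like and for pregranulosa-like cells. With clusters named without the condition on top genes (added) it gave 0.0664 for pregranulosa-like cells. Of the values of called genes under all settings 693 kept direction and call, 326 lost the call and 2 turned round; of those of called lists 239 kept both and 70 lost the call. Values of genes and lists not called stayed so in 1962 and 1417 cases and passed in 72 and 37. The causes were not tested. An alternative written for count data was not run, since the values are not counts. No paired analysis was possible because capture numbers only give an order within a stage, which concerns the stage comparisons; classes were compared within captures. Depth limits the second E12.5 capture most, at an estimated median of 0.152M reads per cell.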

Other observations

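The genes and lists in this part were chosen only after their values were seen. Mest, an imprinted gene on another chromosome (chromosome 6, 30723547 to 30748465), was among the 17 genes lower at P6, at 140 ± 30.9 RPKM at E16.5 and 31.1 ± 1.498 at P6 (SD, n = 2 each; log2 change -2.12 ± 0.25, limma adjusted p = 0.0295). Sugct and Chodl, which rose between E13.5 and E16.5, were among these 17 as well. Steroidogenic genes were already measured early: Star, which carries cholesterol into mitochondria, stood at 4.19 RPKM at E10.5 and 20.5 ± 1.96 at E11.5 (n = 2), and Cyp11a1 passed between these stages when adjusted over the steroidogenic list alone (log2 change 3.55 ± 0.63) and not over all genes (limma adjusted p = 0.0646). Cyp19a1, the aromatase gene, stood at 0.00282 ± 0.00399 RPKM at E16.5 and 15.6 ± 12.8 at P6 (limma adjusted p = 0.0515), and Fshr, the receptor gene of follicle-stimulating hormone, was listed at 0 at E16.5 and stood at 3.91 ± 5.53 at P6 (limma adjusted p = 0.653). In fits that left 1 P6 capture, Cyp19a1 had a log2 change of 2.92 without the first P6 capture and 4.679 without the second, so it rose in either. Fshr had a log2 change of 3.141 without the second P6 capture. Mest was lost without the first E13.5 capture (adjusted p = 0.0768 in limma).

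Sox9, a Sertoli cell gene, stood at 7.14, 9.12 and 4.45 RPKM in the 3 E12.5 captures and at 22.9 RPKM at E10.5. The capture with Y-linked transcripts had the highest of the E12.5 values, 9.12 RPKM. Amh was listed at 0 in all 3 E12.5 captures.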
